A study of Mus musculus with 6 samples.

How the data were processed

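RNA sequencing of lung ILC2s was analysed in 6 samples, 3 WT and 3 Cd48 KO, grouped by the sample titles. Per the labels' protocols, RNA was extracted from cultured cells with a column kit, 10 pg per sample was turned into cDNA with the SMARTer Ultra Low Input v3 kit, and per the design text the libraries were read on a NextSeq 500. The submitters' processing notes name STAR 2.7.8, Partek 10.0, DESeq2 and the mm10 build, without saying which step each served. The gene counter, the annotation, and whether reads were counted by strand are not given in the sources used here.

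The authors deposited estimated counts per gene, without normalization, as judged from the values: none lie below 0, library totals all differ, and 60.2% of the non-zero values are whole within 0.001. Fractional values arise where reads are shared among genes or transcripts. The table has 17438 genes, and the lowest gene total over the samples is 10. The estimated counts were rounded to whole numbers before testing. Library totals ran from 14928623 to 27450400 counts. Of the gene symbols, 17022 (97.6%) matched the GRCm38 annotation, from which positions (1-based), transcript lengths and overlaps were taken, and 416 did not. The length of a gene is that of its longest annotated transcript.

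Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit with robust empirical Bayes, TMM normalization, genotype as the only term). Genes were kept by filterByExpr (minimum count 10, minimum total 15), and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. Standard errors (SE) were derived from the same fit, as the size of the log2 fold change over the square root of its F statistic. Levels are CPM, that is counts scaled by edgeR's cpm function to library sizes adjusted by TMM over the 6 libraries. Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the group. PCR reads without molecular identifiers are not independent molecules, so such bounds cover counting error only. Replicates of each genotype were compared by a chi-square of their counts over genes: no pair agreed within sampling noise, with values per gene from 5.55 to 156, so each sample counted once.

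A total of 40 gene lists, the rule for named genes, the main tests and the first set of alternatives were fixed before the data were examined. Of the lists, 13 were markers of other cell types that a sort could hold. The 31 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided), adjusted over the lists. They were tested again with the correlation estimated for each list, and with fry, whose directional form asks whether a list moves 1 way and whose mixed form asks whether its genes change in either direction. Members were counted past the threshold over all genes and with the adjustment over the list alone. Calls among the listed chromosome 1 neighbours of Cd48, without Cd48, were set against all other tested genes by a two-sided Fisher's exact test.

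The rule for named genes takes Cd48, then up to 12 rises and 12 falls with the largest log2 fold change among called genes with a mean of at least 10 CPM and no overlap between the groups, which chance gives for 10% of genes with 3 against 3 libraries and 20% with 2 against 3. Predicted genes, pseudogenes, receptor segments and sex chromosome transcripts are passed over. It adds up to 4 called members of each list, and the 6 most abundant members of the ILC2 identity, effector and SLAM family lists. With all 6 libraries 3 genes passed, and without WT1 206 passed, of which 8 were passed over. Genes named outside the rule are said to be so. Opposite-strand genes overlap Wdfy1, Gata3, Il5, Furin, Csf2, Ptpn6, Loxl2, Neb, Dscaml1, Ppox, Dcaf8, Ccne2, Prc1, Tpi1, Bnip3, Hif1a, Idi1, Sqstm1 and H2-T22, and their reads cannot be separated from those genes with certainty.

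Other settings were chosen in advance, namely other size factors, no filter and a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom with and without sample quality weights, a fit that was not robust, other thresholds (an adjusted p of 0.1, a 2-fold change, a test against a 1.5-fold change), the replicate number as a block, windows of 1, 5 and 20 Mb around Cd48, and each library left out in turn. After the data had been seen, a trend on transcript length (lowess, span 0.3) in the offsets, the fit without WT1 read in full with its own alternatives, and the rule for named genes on that fit were added. Where 1 WT library was left, it was assumed to vary like the KO libraries. Log2 CPM for correlations and principal components used a prior count of 2.

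The tests were run on simulated counts made from the real means, library sizes and fitted dispersions, with known changes in some genes. For the comparison of all 6 libraries (13028 genes tested), 2%, 24% and 80% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 4 false calls. For the comparison without WT1 (13377 genes tested), 54%, 70% and 96% were recovered, with 13 false calls. In the simulation genes varied independently and WT1 was drawn like any other library. These figures therefore do not cover correlated genes or the trend of WT1 on transcript length. Reads were not analysed here, so exon use and strain variants were left out.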

Results

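RNA was sequenced from group 2 innate lymphoid cells (ILC2s), lymphocytes of barrier tissues that answer the alarm cytokine IL-33 by releasing IL-5 and IL-13. Per the labels, the cells were sorted from mouse lung, treated with IL-33 and cultured. The 2 genotypes were wild type (WT, n = 3) and a targeted Cd48 allele (Cd48 KO, n = 3), whose name gives a donor strain other than the B6 background. The design text of the series speaks of duplicates, whereas 3 samples of each genotype were given here. Deposited counts summed to 14931769, 14928623 and 27450400 in WT1, WT2 and WT3. They summed to 16336449, 16135210 and 17600475 in KO1, KO2 and KO3. Between 15315 genes (WT1) and 17006 genes (WT3) had at least 1 count. The labels do not say that the samples came from separate animals, so every p-value measures the spread between these samples, which may be partly technical.

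The comparison of Cd48 KO with WT asked which transcripts of IL-33-treated ILC2s differ when the SLAM family receptor CD48, a GPI-anchored ligand of CD244 and CD2, is disrupted. The Cd48 transcript (GRCm38/mm10 chromosome 1, 171682009 to 171705258, plus strand) fell in every KO library. Its level was 58.2, 46.6 and 41.6 CPM (counts scaled to library size) in WT1, WT2 and WT3, and 4.52, 5.59 and 4.40 CPM in KO1, KO2 and KO3. The group means were 48.8 ± 8.51 CPM (SD, n = 3) in WT and 4.84 ± 0.657 CPM (SD, n = 3) in KO, a log2 fold change of -3.33 (SE 0.20). The adjusted p was 0.00285 in edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment. The table holds no counts per exon, so the part of the transcript behind the 74, 91 and 78 remaining reads was not analysed here.

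With all 6 libraries, 4 of 13317 tested genes were called, 2 higher and 2 lower in KO, and each had an adjusted p of 0.00285 (edgeR, BH). Besides Cd48, Ifi209 fell. This member of the interferon-inducible HIN-200 family of DNA sensors lies on chromosome 1 (173630917 to 173647928, plus strand) near Cd48. Ifi209 stood at 20.4 ± 0.643 CPM (SD, n = 3) in WT and 1.17 ± 0.241 CPM (SD, n = 3) in KO, a log2 fold change of -4.12 (SE 0.22). Wdfy1, which encodes an endosomal adaptor of Toll-like receptor signalling (chromosome 1, 79702262 to 79776143, minus strand), rose from 9.06 ± 0.532 to 46.3 ± 1.597 CPM (SD, n = 3). Its log2 fold change was 2.35 (SE 0.13). Fn3krp, which encodes a kinase that removes sugar adducts from proteins (chromosome 11, 121421401 to 121431288, plus strand), rose from 0.592 ± 0.117 to 10.98 ± 1.25 CPM (SD, n = 3). Its log2 fold change was 4.19 (SE 0.25), and it was named after its values were seen. Wdfy1 overlaps Mrpl44 on the opposite strand and Ifi209 has close relatives, so reads of these pairs cannot be told apart with certainty. At an unadjusted p under 0.05 there were 918 genes, and DESeq2 called 102 genes on the same libraries. Without KO1, edgeR called 0 genes (662 at an unadjusted p under 0.05), with adjusted p of 0.0754 for Cd48, 0.0594 for Ifi209 and 0.0646 for Wdfy1 and Fn3krp. Without KO3 it also called 0 genes (335 at an unadjusted p under 0.05), with adjusted p of 0.0775 for Cd48 and 0.0544 for the others. Without WT1 it called 248 genes.

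**Figure D1:**
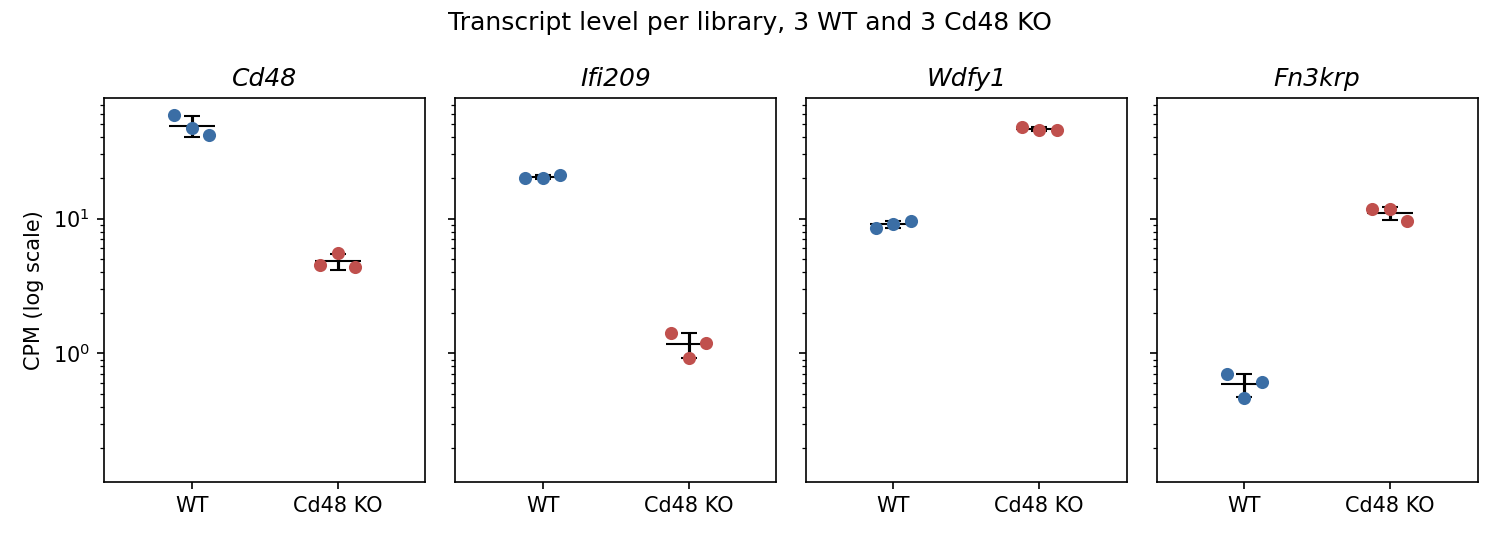
Levels of the 4 genes called with all 6 libraries, as CPM on a log axis, with 1 point per library, WT in blue and Cd48 KO in red, and the mean and SD of each group. Cd48 and Ifi209 lie lower in all 3 KO libraries than in any WT library, and Wdfy1 and Fn3krp lie higher.

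Of 33 measured members of the ILC2 identity list, 0 passed the edgeR test over all genes with all 6 libraries and 0 passed when adjusted over the list alone. On the same libraries limma-voom with sample quality weights called Il2ra higher (adjusted p 0.0426, BH). Gata3, the master transcription factor of the lineage, was at 1205 ± 186 CPM in WT and 934.3 ± 154 CPM in KO (SD, n = 3). Il1rl1, the IL-33 receptor, was at 1026 ± 362 and 1334 ± 15.3 CPM (SD, n = 3). The other abundant members, Cxcr6, Il2ra, Ly6a and Id2, had log2 fold changes of -0.28, 0.32, -0.09 and 0.06. Of 24 effector products, 0 passed the edgeR test over all genes, and 1 higher and 1 lower passed when adjusted over the list alone. DESeq2 and limma-voom with sample quality weights called Calca higher (adjusted p 2.78e-06 and 0.00475, BH) and Ltb lower (0.0205 and 0.0240). Il5 was at 7261 ± 2396 CPM in WT and 7170 ± 419 CPM in KO (SD, n = 3). Il13 was at 281.2 ± 68.4 and 320.3 ± 33.2 CPM (SD, n = 3). Furin, Csf2, Cxcl3 and Tgfb1 had log2 fold changes of 0.36, -0.28, 0.14 and -0.06. The adjusted p of the list test (limma camera, BH) was 0.738 for ILC2 identity and 0.357 for effector products. Camera placed the identity list higher, with a median log2 fold change of 0.06 and a mean of -0.02. Among the most abundant members of the SLAM family list, Sh2d2a, Inpp5d, Cd84, Fyn, Ptpn11 and Ptpn6 had log2 fold changes of -0.01, 0.24, 0.21, -0.45, 0.21 and 0.03, and none passed the edgeR test.

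Across 31 gene lists tested on the 6 libraries, camera with a preset correlation of 0.01 called 4 higher and 10 lower in KO. The higher lists were mitotic (G2/M) genes, mitochondrially encoded genes, glycolysis and hypoxia. All 30 mitotic genes had positive log2 fold changes, with a median of 0.43 (adjusted p 3.33e-12, limma camera, BH). The adjusted p was 0.117 with an estimated correlation. The medians were 0.64 for the 13 mitochondrially encoded genes, 0.30 for 23 glycolysis genes and 0.18 for 23 hypoxia genes, with adjusted p of 4.25e-08, 5.64e-05 and 0.00268 (limma camera, BH). With an estimated correlation these adjusted p were 0.348, 0.348 and 0.117. A filter at a mean of at least 10 CPM ended the hypoxia call (adjusted p 0.0506). Without WT1 the medians were 0.35 for mitochondrially encoded genes and 0.16 for glycolysis. Over all genes 0 members of these lists passed the edgeR test, and adjusted over the list alone 10 mitotic, 0 mitochondrially encoded, 1 glycolysis and 2 hypoxia genes passed, each higher. Interferon-response genes were lower, with a median of -0.33 over 36 members (adjusted p 1.66e-07, limma camera, BH), and adjusted p = 0.117 with an estimated correlation. MHC class I antigen presentation was lower, with a median of -0.28 over 18 members (adjusted p 4.25e-05), and adjusted p = 0.117 with an estimated correlation. MHC class II presentation (adjusted p 0.00413), oxidative phosphorylation (1.91e-05) and ribosomal proteins (0.00377) were lower too. With an estimated correlation these had adjusted p of 0.133, 0.485 and 0.464. Adjusted over the list alone, 7 interferon-response, 3 MHC class I and 1 MHC class II genes passed, each lower, with 0 oxidative phosphorylation and 0 ribosomal genes.

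The SLAM family list was called lower (adjusted p 0.000377, limma camera, BH; adjusted p = 0.117 with an estimated correlation). Its 10 members had a mean log2 fold change of -0.41 and a median of 0.01. Cd48 was the only member that edgeR called over all genes, and 2 members, both lower, passed when adjusted over the list alone. DESeq2 and limma-voom with sample quality weights also called Ly9 lower (adjusted p 0.0477 and 0.0164, BH), and the latter called Slamf1 higher (0.0324). Without the members that lie near Cd48 the adjusted p of this list was 0.620. The list of chromosome 1 neighbours of Cd48 was called lower (adjusted p 0.0360, limma camera, BH; adjusted p = 0.356 with an estimated correlation), with a mean of -0.30 and a median of 0.07 over 45 members. Leaving out WT2, WT3, KO2 or KO3 ended that call (adjusted p 0.203, 0.236, 0.0723 and 0.118), and so did a filter at a mean of at least 10 CPM (0.0679). Leaving out WT2 ended the call of MHC class II (adjusted p 0.137). Leaving out WT3 or KO1 ended that of ribosomal proteins (adjusted p 0.0610 and 0.133), and so did removing the trend of each library on transcript length (adjusted p 0.813). In total 17 lists were not called. Among them were targets of NF-κB, of IL-2 and STAT5, and of AP-1 with immediate early genes, S phase, apoptosis and survival, fatty acid metabolism and cholesterol synthesis. The others covered the unfolded protein response, heat shock, autophagy and lysosome, checkpoint and costimulation, chemotaxis and adhesion, TGF-β and tissue residency, and PI3K and mTOR signalling, besides endothelial markers and the ILC2 identity and effector lists. Their adjusted p ranged from 0.0571 (IL-2 and STAT5 targets) to 0.738 (ILC2 identity), and S phase was placed higher with a median log2 fold change of 0.03 and a mean of -0.03. Without WT1, S phase, NF-κB targets, IL-2 and STAT5 targets and cholesterol synthesis were called higher (adjusted p 0.00134, 0.0345, 0.0179 and 0.000239, limma camera, BH). With an estimated correlation their adjusted p were 0.199, 0.188, 0.206 and 0.193. IL-2 and STAT5 targets were also called without KO2 (adjusted p 0.0354), and AP-1 and immediate early genes without KO1 (0.0175).

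WT1 stood apart from the other 5 libraries. Pearson's r of log2 CPM across genes was 0.922 to 0.932 for pairs with WT1 and 0.980 to 0.988 for pairs without it, and the first principal component, with 68.3% of the variance, separated WT1 from the rest. Long transcripts were under-represented in WT1. Its median log2 difference from WT2 and WT3 was 0.32 for transcripts of 500 to 1000 bases and -0.91 for those of at least 8000 bases. Spearman's rho of this difference with transcript length was -0.348 across 13053 genes, which are not independent replicates. Mitochondrially encoded genes took 0.264% of the counts in WT1, 0.619% and 0.535% in WT2 and WT3, and 0.678%, 0.737% and 0.777% in KO1, KO2 and KO3. Il5 took 0.960% in WT1 and 0.568% to 0.770% in the other libraries. The common biological coefficient of variation was 0.258 with all 6 libraries and 0.109 without WT1. Leaving out each library in turn had been planned; reading the fit without WT1 in full was chosen after the difference had been seen.

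**Figure D2:**
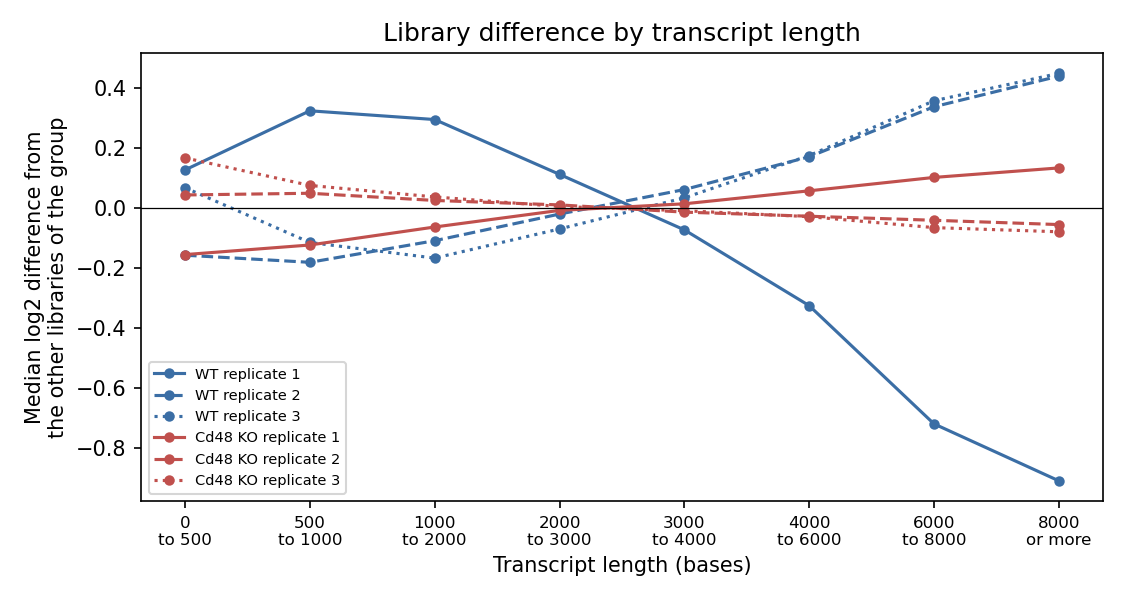
Median log2 difference of each library from the other libraries of its group, by transcript length in bases, with WT in blue and Cd48 KO in red. The line of WT1 falls to -0.91 at the longest transcripts, and those of WT2 and WT3, each set against a mean that includes WT1, run the other way.

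Without WT1 (2 WT against 3 KO libraries), 248 of 13643 genes were called by edgeR, 159 higher and 89 lower in KO, and 1865 had an unadjusted p under 0.05. The 4 genes called with all libraries were among them. Of 27 checkpoint and costimulation genes 1 rose (Tnfrsf9), 1 fell (Tnfsf4) and 25 did not pass over all genes, and 2 rose and 1 fell when adjusted over the list alone. The list was not called (adjusted p 0.941, limma camera, BH) and was placed lower with a median log2 fold change of -0.02 and a mean of 0.03. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose from 205.5 ± 39.9 (SD, n = 2) to 419.0 ± 43.8 CPM (SD, n = 3). Its log2 fold change was 1.03 (SE 0.14), with an adjusted p of 0.0321 (edgeR, BH). Tnfsf8, the CD30 ligand, rose with a log2 fold change of 0.94 (SE 0.12). Tnfsf4, the OX40 ligand, fell from 146.7 ± 3.965 (SD, n = 2) to 84.5 ± 5.17 CPM (SD, n = 3), a log2 fold change of -0.79 (SE 0.08) with an adjusted p of 0.000177 (edgeR, BH). Tgtp1, Tgtp2 and Gbp6, which encode interferon-inducible GTPases, had log2 fold changes of -1.55, -0.99 and -1.12. Tgtp1 and Tgtp2 are near-identical and Gbp6 has close relatives, so how their reads were divided is uncertain. Prdx6, a peroxidase that reduces lipid peroxides, fell from 794.4 ± 46.8 (SD, n = 2) to 471.3 ± 3.27 CPM (SD, n = 3), with a log2 fold change of -0.75 (SE 0.05). Prnp, the prion protein, rose from 125.0 ± 2.75 (SD, n = 2) to 240.2 ± 4.39 CPM (SD, n = 3), with a log2 fold change of 0.94 (SE 0.06).

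The other large rises without WT1, among called genes with a mean of at least 10 CPM and no overlap between the groups, were Adgrf5 (log2 fold change 1.29), the collagen cross-linking enzyme gene Loxl2 (1.25), the muscle filament gene Neb (1.16), Dscaml1 (0.94), Rab31 (0.87), Csgalnact1 (0.87) and the cell division genes Cenpn (0.86) and Aspm (0.82). The other large falls among them were Ly9 (-1.11), the haem synthesis gene Ppox (-0.94), the CD3 subunit gene Cd3g (-0.92), Smpdl3a (-0.91), the lymphocyte GTPase gene Gimap4 (-0.84) and the epithelial adhesion gene Epcam (-0.83). Ppox overlaps B4galt3 on the opposite strand. Of the 248 genes, 242 were tested with all 6 libraries, 235 of these in the same direction and 176 with an unadjusted p under 0.05. The value of WT1 lay on the WT side of every KO library for 201 of the 248 genes. The same share over all tested genes was not taken, so this count has no baseline. With all 6 libraries DESeq2 called 81 of the 248, and limma-voom with sample quality weights called 93, giving WT1 a weight of 0.0919 and the others 1.08 to 2.36. The fits with all 6 libraries reuse the libraries that gave the 248 calls. Their shared directions, low p-values and shared calls are therefore no independent support. Leaving out a further library gave 89 genes without WT2, 141 without WT3, 517 without KO1, 73 without KO2 and 65 without KO3. Of these, 71, 86, 230, 69 and 63 were among the 248. Of the 24 genes with the largest rises and falls among called genes with a mean of at least 10 CPM and no overlap between the groups, 14 were called in each of these 5 fits. Leaving out WT2 ended the calls of Cd3g, Ly9, Rab31, Csgalnact1, Cenpn and Epcam, and leaving out WT3 ended those of Cenpn, Epcam, Gimap4 and Neb. Leaving out KO2 ended those of Cenpn, Csgalnact1, Epcam and Neb, and leaving out KO3 ended these and those of Adgrf5, Gimap4 and Tnfrsf9.

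Mitotic genes were higher in KO without WT1. Of 30 measured members 17 rose, 0 fell and 13 did not pass over all genes, and 27 rose when adjusted over the list alone. Examples were the kinetochore gene Cenpf (log2 fold change 0.80, SE 0.11), the spindle genes Hmmr (0.64, SE 0.10) and Kif23 (0.58, SE 0.09) and the midzone gene Prc1 (0.54, SE 0.09). Cenpf lies 17.9 Mb from Cd48 on chromosome 1. The adjusted p of the list was 5.70e-35 (limma camera, BH), and adjusted p = 0.166 with an estimated correlation. Of 27 S phase genes 3 rose, both over all genes and adjusted over the list alone, namely the ribonucleotide reductase genes Rrm1 (0.31) and Rrm2 (0.30) and the cyclin gene Ccne2 (0.45). The list had an adjusted p of 0.00134 (limma camera, BH; adjusted p = 0.199 with an estimated correlation), and 0.101 when WT3 was also left out. Rrm2 and Ccne2 had log2 fold changes of -0.07 and -0.04 with all 6 libraries, neither past the test.

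The MHC class I antigen presentation list was lower without WT1, but not through all its members. Of 18 members 9 fell, 0 rose and 9 did not pass over all genes, and 14 fell when adjusted over the list alone. The 9 that fell over all genes were H2-K1, H2-D1, H2-Q6, H2-Q7, H2-T22, H2-T23, Psmb9, Tap1 and Tapbp. Among the 9 that did not pass were B2m (-0.17), Psmb10 (-0.24), Erap1 (-0.14) and Nlrc5 (0.008), with adjusted p of 0.129, 0.230, 0.428 and 0.981 (edgeR, BH). H2-K1, a classical class I heavy chain gene, fell from 3359 ± 175 (SD, n = 2) to 2466 ± 39.1 CPM (SD, n = 3), a log2 fold change of -0.44 (SE 0.05) with an adjusted p of 0.000370 (edgeR, BH). H2-T22 fell by 0.46 on the log2 scale, and H2-Q6 and H2-Q7, which share sequence and are uncertain, had log2 fold changes of -0.49 and -0.51. The list had an adjusted p of 6.17e-18 (limma camera, BH), and adjusted p = 0.0981 with an estimated correlation. Of 37 interferon-response genes 6 fell and 0 rose over all genes, and 12 fell when adjusted over the list alone. They included the immunity-related GTPase genes Igtp (-0.50), Irgm1 (-0.42) and the guanylate-binding protein gene Gbp4 (-0.42), whereas the related Gbp2, Gbp3, Gbp5, Gbp7 and Irgm2 did not pass. Igtp overlaps Irgm2, and Gbp4 overlaps Gbp8 and Gbp9, on the same strand. Iigp1 had 0 counts in all 3 KO libraries and was at least 24.8-fold lower than in WT2 and WT3, against a floor of 3 counts over the KO group, which covers counting error only. The list had a median of -0.28, which is the same with Iigp1 at its bound, and an adjusted p of 3.56e-12 (limma camera, BH; adjusted p = 0.0981 with an estimated correlation). MHC class II presentation fell (adjusted p 0.00126, limma camera, BH; adjusted p = 0.178 with an estimated correlation), with Cd74 (-0.58) and Ctss (-0.62) the members called, both over all genes and adjusted over the list alone. Leaving out WT2 as well ended this call (adjusted p 0.0645). In the same libraries, summed markers of T cells, macrophages and epithelium were also lower in KO, at 410.5, 495.1 and 88.2 CPM in WT2 and WT3 and 340.5, 289.1 and 22.98 CPM in KO. Of the 206.0 CPM lost by macrophage markers, Ccr2 gave 82.9 and Chil3 98.1 CPM, and Chil3 did not pass (adjusted p 0.727, edgeR, BH). Zap70, the most abundant T cell marker, had a log2 fold change of 0.05 and did not pass, whereas Cd3g and Trbc2 were called lower. The sums were not read as numbers of cells.

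Some members of the hypoxia and glycolysis lists rose without WT1. Of 23 hypoxia genes 5 rose, 0 fell and 18 did not pass over all genes, and 9 rose when adjusted over the list alone. The 5 included Epas1 (0.62, SE 0.09) and Hif1a (0.32, SE 0.05), which encode HIF-2α and HIF-1α, the mitophagy receptor gene Bnip3 (0.67, SE 0.11) and the oxidase gene Ero1l (0.26, SE 0.04). Among the 18 were Vegfa (0.17), Adm (0.44), Car9 (0.31) and Ndrg1 (-0.05). The adjusted p of the list was 3.20e-07 (limma camera, BH), and adjusted p = 0.0981 with an estimated correlation. Of 23 glycolysis genes 4 rose, 0 fell and 19 did not pass over all genes, and 7 rose when adjusted over the list alone. The 4 were the lactate exporter gene Slc16a3 (0.64), Pfkl (0.44), Tpi1 (0.32) and Pgam1 (0.25). Among the 19 were Pgk1 (0.005) and Ldha (0.25). The adjusted p of the list was 5.53e-07 (limma camera, BH), and adjusted p = 0.178 with an estimated correlation. Of 32 fatty acid metabolism genes 5 rose over all genes, among them Scd2 (0.39) and Dgat2 (0.35), and 8 rose and 1 fell when adjusted over the list alone, though the list was not called (adjusted p 0.265, limma camera, BH) and was placed higher with a median of -0.03 and a mean of -0.05. Cholesterol synthesis was called higher (adjusted p 0.000239, limma camera, BH; adjusted p = 0.193 with an estimated correlation), with Idi1 (0.33) and Hsd17b7 (0.50) called over all genes and 3 genes adjusted over the list alone. Hsd17b7 is a listed neighbour of Cd48, 1.71 Mb from it, and the cholesterol list was not retested without it in this fit. Of the 13 mitochondrially encoded genes, mt-Cytb (0.43) and mt-Nd1 (0.36) rose over all genes and 10 rose when adjusted over the list alone. The list had an adjusted p of 1.96e-11 (limma camera, BH; adjusted p = 0.178 with an estimated correlation). Oxidative phosphorylation and ribosomal proteins were called lower (adjusted p 0.0154 and 3.20e-07, limma camera, BH; adjusted p = 0.690 and 0.536 with an estimated correlation), with 0 members called by edgeR over all genes or adjusted over the list alone. The oxidative phosphorylation call ended when WT2 or KO1 was also left out (adjusted p 0.148 and 0.544), and when the trend on transcript length was removed (adjusted p 0.318).

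Members of the effector products list went in both directions without WT1. Over all genes 2 of 25 rose, 2 fell and 21 did not pass, and adjusted over the list alone 3 rose and 3 fell. Il5 rose from 5888 ± 412 (SD, n = 2) to 7170 ± 419 CPM (SD, n = 3), a log2 fold change of 0.29 (SE 0.06) with an adjusted p of 0.0332 (edgeR, BH). Over 12 alternatives to this fit its log2 fold change ran from 0.21 to 0.35, and the call did not hold in all of them. In WT1 Il5 stood at 10007 CPM, above every KO library, and the log2 fold change with all 6 libraries was -0.02. Calca, which encodes the neuropeptide CGRP, rose with a log2 fold change of 0.75 (SE 0.09). Ltb, which encodes lymphotoxin β, fell by 0.63 (SE 0.10) on the log2 scale, and Ccl9 had a log2 fold change of -1.39 (SE 0.31). Il13 had a log2 fold change of 0.40 (SE 0.10) and did not pass (adjusted p 0.0845, edgeR, BH). Of 33 ILC2 identity genes 2 rose, the IL-2 receptor gene Il2ra (0.31) and the decoy receptor gene Il1r2 (0.42), and 31 did not pass over all genes, with the same counts adjusted over the list alone. The camera adjusted p (limma, BH) was 0.982 for the identity list and 0.941 for effector products, and the latter was 0.0430 when WT2 was also left out. Camera placed effector products higher, with a median of -0.02 and a mean of -0.19. Targets of NF-κB were called higher (adjusted p 0.0345, limma camera, BH; adjusted p = 0.188 with an estimated correlation), with Tnfrsf9, Il2ra and Map3k8 (0.46, and 0.02 with all 6 libraries) up over all genes, and 4 higher and 1 lower adjusted over the list alone. Leaving out WT3, KO1 or KO3 as well ended that call (adjusted p 0.0549, 0.1003 and 0.0663). Targets of IL-2 and STAT5 were called higher (adjusted p 0.0179, limma camera, BH; adjusted p = 0.206 with an estimated correlation), with Il2ra, Osm (0.49) and the barely detected Gzmb up over all genes and adjusted over the list alone. Leaving out WT3 or KO1 as well ended that call (adjusted p 0.142 and 0.0869).

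**Figure D3:**
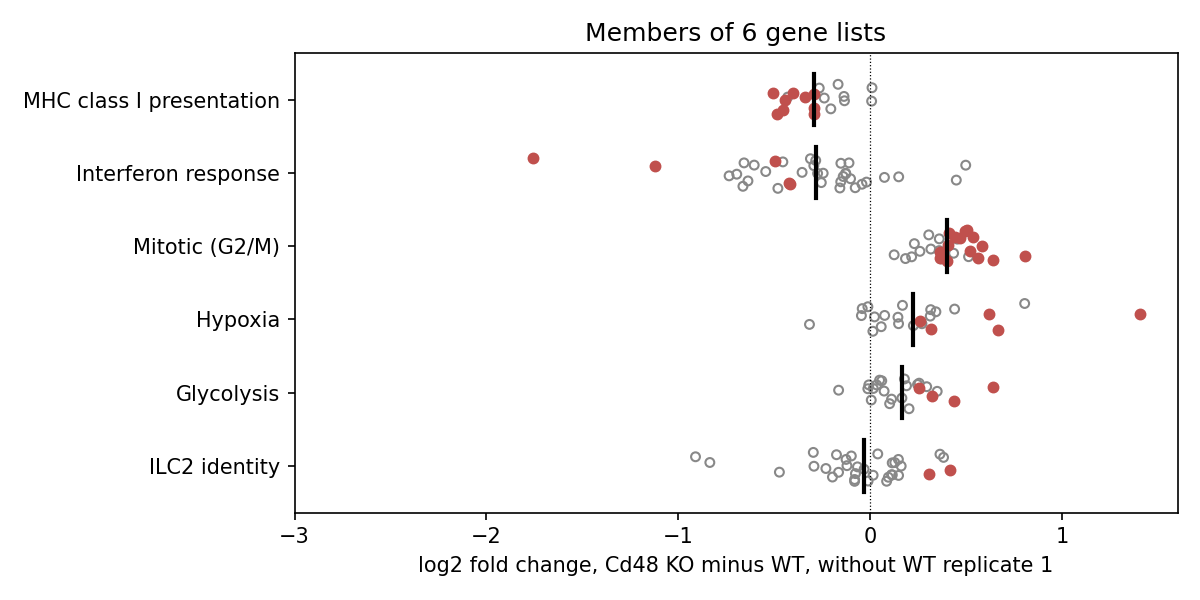
Log2 fold change of each measured member of 6 gene lists in Cd48 KO against WT without WT1, on the horizontal axis, with 1 point per gene, called genes in filled red, others open and grey, and a bar at each list's median. The mitotic members all lie above 0, 16 of 18 MHC class I members lie at negative values, and 1 member of the interferon-response list, Iigp1, lies beyond the axis.

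Genes called near Cd48 were counted apart, since a donor segment can stay linked to a targeted allele. With all 6 libraries 1 of 45 listed neighbours (Ifi209, Cd48 itself left out) and 2 of 13271 other genes were called by edgeR, an odds ratio of 150 (exact two-sided Fisher p 0.0101). Without KO1 or KO3 the number was 0 (edgeR, with 662 and 335 genes at an unadjusted p under 0.05), and without WT1 it was 12. Without WT1 the 12 of 47 neighbours called (25.5%) compared with 235 of 13595 other genes (1.73%), an odds ratio of 19.5 (95% interval 9.08 to 39.0, exact two-sided Fisher p 2.83e-11). Adjusted over the list alone, 7 neighbours were higher and 12 lower, and camera called the list lower (adjusted p 0.00134, limma, BH; adjusted p = 0.166 with an estimated correlation). Over all genes Slamf1, Hsd17b7, Pea15a and Ifi204 were higher, and Ly9, Ppox, Ncstn, Pex19, Dcaf8, Dusp23, Ifi206 and Ifi209 were lower. Slamf1, Ly9, Ppox, Ifi206 and Ifi204 were singled out after their values were seen. Of 11 SLAM family genes, Slamf1 rose and Cd48 and Ly9 fell, both over all genes and adjusted over the list alone (list adjusted p 3.65e-05, limma camera, BH; adjusted p = 0.152 with an estimated correlation). The SLAM family list holds Cd48 itself and was not retested without the members near Cd48 in this fit. With all 6 libraries its adjusted p without them was 0.620 (limma camera, BH). Ly9, the SLAM receptor gene beside Cd48, fell from 16.0 ± 1.75 (SD, n = 2) to 7.36 ± 0.864 CPM (SD, n = 3). Slamf1 was at 0.731 ± 0.116 CPM in KO (SD, n = 3), at 0 and 0.0359 CPM in WT2 and WT3 and at 1.68 CPM in WT1, and with WT1 included edgeR did not call it (adjusted p 0.893, BH), whereas limma-voom with sample quality weights did (adjusted p 0.0324, BH). Ifi206 had 0 counts in the KO libraries and was at least 47.9-fold lower than in WT2 and WT3, against the floor of 3 counts over the group. Ifi204 was at 1.48 ± 0.333 CPM in KO (SD, n = 3), at 0 CPM in WT1 and WT2 and at 0.179 CPM in WT3. Reads of the related Ifi204, Ifi206 and Ifi209, and of Dcaf8 and Pea15a on opposite strands, may have been assigned to either partner. Leaving out another library gave 5 called neighbours without WT2, 7 without WT3, 6 without KO2 and 5 without KO3. Tnfsf4, Prdx6 and Gas5, each lower, lie 10.3, 10.4 and 10.6 Mb from Cd48, and Wdfy1 lies 91.9 Mb from it. Within 20 Mb of Cd48, itself left out, 18 of 231 genes were called without WT1 (7.79%, against 1.71% elsewhere, exact two-sided Fisher p 2.12e-07), these 3 genes among them. Of the 18, 13 lay within 5 Mb. From 5 to 20 Mb, listed neighbours left out, 5 of 165 genes were called, an odds ratio of 1.80 (exact two-sided Fisher p 0.212). Chromosome 1 without Cd48 held 31 calls among 813 genes (3.81%, against 1.71% elsewhere), with an exact Fisher p of 0.00256 after BH adjustment over the chromosomes. Among these 31 were Gm28437, Gm10925 and Gm28661, adjacent unprocessed pseudogenes 147 Mb from Cd48, whose reads may belong to related genes. The 13 calls within 5 Mb of Cd48 are among the 31 as well. The value for the chromosome therefore partly restates the pattern near Cd48 and does not show a change along the whole chromosome. Chromosome 17 had the next lowest unadjusted p, with 20 calls among 658 genes (3.04%, against 1.78% elsewhere). Its exact Fisher p was 0.222 after BH adjustment.

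**Figure D4:**
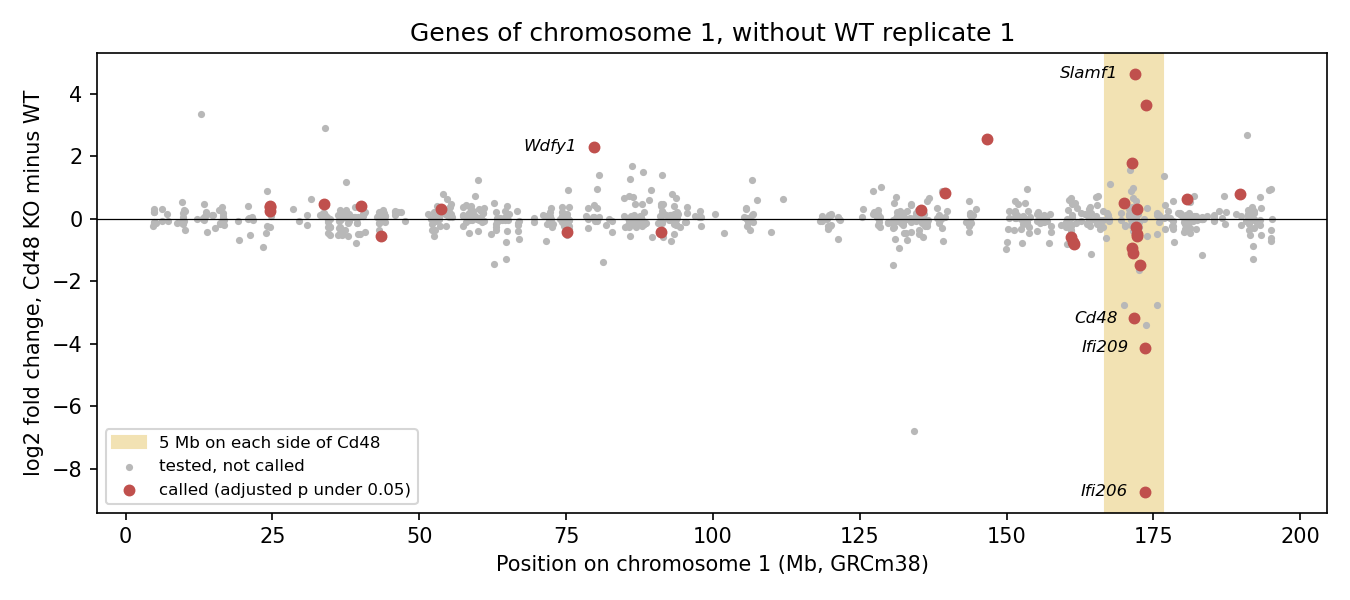
Log2 fold change in Cd48 KO against WT without WT1 for genes on chromosome 1, by position in megabases of GRCm38, with called genes in red, others in grey and 5 Mb on each side of Cd48 shaded. The called neighbours of Cd48 lie on both sides of 0, and the point of Ifi206, with 0 counts in KO, is a fitted value and not a bound.

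Markers of other cell types were low in every library. The highest summed level in WT1 was 633.9 CPM for stromal markers, of which Gsn, an actin-severing protein gene of many cell types, gave 632.6 CPM. T cell, macrophage and epithelial markers were called lower in KO with all 6 libraries (adjusted p 0.000130, 0.0109 and 0.000798, limma camera, BH). With an estimated correlation their adjusted p were 0.178, 0.446 and 0.117. Leaving out WT2, WT3 or KO3 ended the macrophage call (adjusted p 0.103, 0.187 and 0.138). Over all genes edgeR called 0 members of these lists, and adjusted over the list alone 3 T cell, 1 macrophage and 1 epithelial genes passed, each lower. Over all genes Cd3g, Apoe and Epcam were called lower by DESeq2 (adjusted p 0.00323, 0.00323 and 0.0339, BH) and by limma-voom with sample quality weights (0.0164, 0.00867 and 0.0424). Without WT1 the same lists were called lower (adjusted p 2.07e-05, 2.10e-05 and 1.36e-07), with adjusted p of 0.178, 0.180 and 0.166 with an estimated correlation. Cd3g, the T cell receptor constant gene Trbc2 (-0.39), Ccr2 (-0.48), Apoe (-2.21) and Epcam fell, and adjusted over the list alone 4 T cell, 2 macrophage and 4 epithelial genes fell. The airway secretory gene Scgb1a1 was at 1.82, 19.0 and 47.2 CPM in WT1, WT2 and WT3, and 0, 0.184 and 12.9 CPM in KO1, KO2 and KO3. Endothelial markers were not called (adjusted p 0.139 with all libraries and 0.448 without WT1). Too few members of the other 9 lists passed the count filter for a test, and only their summed levels in WT and KO (means of n = 3 each) were taken. These were 34.9 and 29.6 CPM for B cells, 0.822 and 2.73 CPM for NK cells and ILC1s, and 399.7 and 388.5 CPM for ILC3s. Dendritic cell markers summed to 67.9 and 62.4 CPM, neutrophil markers to 3.81 and 3.95 CPM, and eosinophil markers to 3.73 and 2.46 CPM. Mast cell and basophil markers summed to 12.8 and 15.9 CPM, stromal markers to 634.1 and 778.6 CPM, and erythroid markers to 3.69 and 5.28 CPM. Without WT1 the WT sums were 27.9 CPM for B cells, 5.57 CPM for neutrophils and 2.03 CPM for eosinophils, each on the other side of the KO sum.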

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

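The trend on transcript length and all alternatives to the fit without WT1 were chosen after the result was seen; the others were planned. With all 6 libraries, Cd48 stayed lower throughout, and its log2 fold change ran from -3.45 to -3.18 with 1 library left out. DESeq2 size factors, total library size, the upper quartile, no filter, limma-voom, a fit that was not robust and the length trend each called the same 4 genes. The length trend ended 1 list call in each fit, ribosomal proteins with all libraries (adjusted p 0.813) and oxidative phosphorylation without WT1 (0.318; limma camera, BH). DESeq2 called 51 higher and 51 lower with 7 near Cd48, limma-voom with quality weights 51 and 44, and a mean of at least 10 CPM 1 higher, since Fn3krp is not tested then, and 3 lists higher and 6 lower, without hypoxia (adjusted p 0.0506) and the Cd48 neighbours (0.0679; limma camera, BH), while macrophages, epithelium and MHC class II kept too few members to be tested. With estimated correlations 0 lists were called higher and 0 lower (adjusted p 0.117 to 0.811, limma camera, BH). Fry, which compares a list with no other genes, called 2 higher and 5 lower, and 2 and 6 in its mixed form. Within 1 Mb of Cd48 there were 0 calls by edgeR, with 918 genes at an unadjusted p under 0.05. With 1 library left out, called genes ran from 0 to 159 higher and 0 to 89 lower, lists from 4 to 8 higher and 7 to 10 lower, and neighbours of Cd48 from 0 to 12. The ends with 0 were the fits without KO1 or KO3, and the highest counts came without WT1. Without WT1, Il5 (0.29), Rrm2 (0.30), Ccne2 (0.45) and Sqstm1 (-0.22) took the opposite sign; with any 1 library left out they ran from -0.17, -0.24, -0.24 and -0.22 to 0.29, 0.30, 0.45 and 0.17. The labels do not say whether samples were paired by replicate number. Deviations of same-numbered samples correlated at -0.0461, -0.0356 and -0.00911, and no WT sample correlated best with its own number. With so few libraries these correlations cannot tell whether samples were paired. With the number as a replicate block, 0 genes were called higher and 0 lower (edgeR, 776 at an unadjusted p under 0.05), 0 were near Cd48, and Cd48 had a log2 fold change of -3.32 (adjusted p 0.129, edgeR, BH); no list call changed. In the fit without WT1, DESeq2 called 259 higher and 154 lower, an adjusted p of 0.1 gave 263 and 157, a 2-fold minimum 21 and 28, and estimated correlations 0 lists higher and 0 lower (lowest adjusted p 0.0981, limma camera, BH). Leaving out a further library gave 30 to 224 genes higher, 35 to 293 lower, 6 to 9 lists higher, 9 to 10 lower, 5 to 14 neighbours, and -3.30 to -3.11 for Cd48. Apart from the stricter thresholds and filters and the fewer samples, the cause was not tested. Depth limits genes near the floor, such as Slamf1, Gzmb and Ifi204.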

Other observations

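The tests of an exchanged label, of a donor segment, of reads lost in alignment, of mitotic against ILC2 identity genes and of other-cell markers over all lists were chosen after the result was seen; the others were chosen before. Single members changed in lists that were not called without WT1. Pmaip1, which encodes the pro-apoptotic protein NOXA, rose (log2 fold change 0.73, SE 0.11) and was 1 of 32 apoptosis and survival genes called over all genes, with 2 adjusted over the list alone. Dusp6, a phosphatase that switches off ERK, fell by 0.35 (SE 0.06) on the log2 scale and was 1 of 28 AP-1 and immediate early genes called, as it was adjusted over the list alone. That list was called lower when WT2 or KO1 was also left out (adjusted p 0.0378 and 0.00201, limma camera, BH), and heat shock genes were called higher when WT3 or KO2 was (0.0448 and 0.0275). Sqstm1, the autophagy receptor p62, had a log2 fold change of -0.22 (SE 0.05) without WT1 and of 0.02 with all 6 libraries, where it did not pass. Ccr2, a receptor for monocyte-attracting chemokines, fell from 292.5 ± 10.1 (SD, n = 2) to 209.5 ± 5.87 CPM (SD, n = 3), the 1 called of 26 chemotaxis and adhesion genes, with 3 lower adjusted over the list alone. Of 29 unfolded protein response genes and 16 heat shock genes, 0 were called by edgeR without WT1, where 1865 genes in all had an unadjusted p under 0.05 and DESeq2 called 413.

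WT1 held fewer counts from long transcripts than the other libraries. Poorer recovery of long transcripts predicted a rho with length under -0.3 and below that of every other library, and the value was -0.348, with -0.188 for KO3 as the next lowest. An exchange of labels with a KO library was argued against by Cd48, at 58.2 CPM in WT1 and 5.59 CPM in the highest KO library. Cells of another type were argued against by their markers, whose highest list summed to 633.9 CPM. Loss of long RNA or of long cDNA from the very small input may therefore be a candidate explanation for part of the difference; no biological explanation was tested, since WT1 shares its genotype with WT2 and WT3.

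Genes near Cd48 changed more often than others. A donor segment carried along with the targeted allele was tested beyond the listed neighbours, since the enrichment near Cd48 is the pattern itself: 5 to 20 Mb from Cd48 5 of 165 genes were called without WT1, an odds ratio of 1.80 (95% interval 0.571 to 4.35), which leaves the segment open. Loss of donor reads in alignment to the reference would lower counts, but of the 4 called neighbours that were higher in KO only 1, Hsd17b7, had a mean of at least 10 CPM and no overlapping gene, which is too few to argue against it. For the 8 that were lower it cannot be told apart from lower expression, because the table holds no counts per exon. Strain differences in the linked segment and an effect of CD48 on its neighbours both stay open. Wdfy1, 91.9 Mb from Cd48, and Fn3krp, on another chromosome, lie beyond the windows used. Strain differences elsewhere in the genome were not tested.

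Without WT1, camera with the preset correlation called the MHC class I and interferon-response lists lower and the mitotic list higher in KO. Over all genes 9 of 18, 6 of 37 and 17 of 30 members passed the edgeR test. With an estimated correlation these lists had adjusted p of 0.0981, 0.0981 and 0.166 (limma camera, BH). A trend on transcript length was argued against: with the trend removed, the medians were -0.30, -0.30 and 0.37, and the smallest in size, that of MHC class I, was 0.296 in absolute log2 units. Fewer other cells in the KO libraries would have raised ILC2 genes as much as mitotic genes, but the medians of these lists differed by 0.434. For MHC class I, fewer other cells stay open: the 6 other-cell lists that fell lost 0.177 of the 2244 CPM lost by H2-K1 and H2-D1, but these lists were picked by their fall, and the value was 0.0962 without Ccr2 and the uneven Chil3, 0.106 over all 13 lists and 0.0622 to 0.172 over all lists with 1 marker left out, on both sides of the tenth set as the limit. Loss of CD48 itself, the linked segment, strain differences elsewhere in the genome and differences in culture stay open and were not tested against each other. The positions of the called MHC class I genes were not compared as a set, so a change limited to a shared region of the genome stays open.

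The 6 libraries can be split into 3 and 3 in 10 ways, and the 5 without WT1 into 2 and 3 in 10 ways, so neither can give a share under 0.05. With 6 libraries 1 of the 10 splits, the real one, gave as many genes, 4 against at most 0 for the others by edgeR. DESeq2 gave 102 genes for the real split and was not run on the others. Without WT1 again 1 of the 10 splits, the real one, gave as many genes by edgeR, with 248. The others gave at most 99, reached by KO2 and KO3 against the rest.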
